A study of Mus musculus with 6 samples.

How the data were processed

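Gene expression was measured in C2C12 cells on 6 single-colour Agilent arrays labelled with Cy3, 3 from si-NC and 3 from si-SYISL cells, each from 1 µg of total RNA. The deposited scanner files hold intensity, as gProcessedSignal, which Feature Extraction had background-subtracted and spatially detrended within each array and which had not been normalised between arrays. The same deposited files hold the median pixel intensity of each spot and of its local background, and flags of 0 or 1 per spot (unit other, per the file headers) for signal well above background, saturation and outliers. The file headers give Feature Extraction 11.0.1.1, and the authors' processing notes give 10.5.1.1. The deposited series matrix holds log2 values of 34456 probes, and its columns have nearly equal quantiles (median 8.58 on each array), so they were taken as log2 and quantile-normalised by the authors. It was used only as an alternative.

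The 44397 spots of each array were read in R 4.3.3 with the package data.table (version 1.17.8) and with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and figures were drawn with matplotlib 3.10.9. The log2 signals had each array's 75th percentile over non-control spots subtracted, control and outlier spots were left out, and the spots of a probe were averaged. Probes were named through the RefSeq accession printed for them and a list of mouse gene symbols for assembly GRCm38.p6. Of 39429 probes, 27234 were paired with 1 of 20659 gene symbols and 12195 stayed unnamed and stood for themselves. The array design was annotated on another assembly, so no coordinates are given. A probe was kept when it was well above background on all 3 arrays of at least 1 group, and a gene with several kept probes was represented by the one with the highest mean. This left 28555 features. Of these, 1005 were not above background on any si-NC array and 14 not on any si-SYISL array; for such genes the fold is given as a lower bound, computed with the group below background set to no less than the dimmest probe that passed as well above background on each array.

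The fit fixed before the data were examined used the 6 arrays as 6 samples. The arrays were then compared in pairs, from the spread of the 10 spots of each replicated probe, and replicates 1 and 3 of each group differed by less than that spread. They were averaged and counted as 1 sample, so the reported fit has 2 samples in each group. This departure was chosen after the array values were seen. Replicates 1 and 2 of both groups came from 1 scan and replicate 3 of both groups from another.

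Groups were compared with limma 3.58.1 (lmFit and eBayes, default settings, two-sided), with Benjamini-Hochberg adjusted p-values over all features and a threshold of 0.05. Gene lists fixed before the data were examined, 23 in all, were tested with camera at a preset correlation of 0.01, adjusted over the lists, with the same test at an estimated correlation and with fry beside it. The smallest directional fry p adjusted over the lists was 0.105. Unlike the preset test, camera at an estimated correlation rests on the 2 residual degrees of freedom, which leaves it little power. Its smallest unadjusted p over the lists was 0.148. For cell cycle inhibitors the estimated correlation was 0.016, near the preset, yet the unadjusted camera p moved from 0.0306 to 0.172. A call lost in that test therefore cannot be put down to correlation between genes. List members were also adjusted over the list alone. In the reported fit the prior had 2.37 degrees of freedom and the samples 2. The first principal component held 64.5% of the variance and the second 21.6%.

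Named genes followed a rule fixed before the data were examined. When none passes, it takes the 12 higher and 12 lower genes with the smallest p. Only genes with all si-SYISL samples on one side of the si-NC samples were eligible for these. Clone and predicted-gene names were left out. The rule also takes the 2 members with the smallest p of each list, and Synpo2, Myod1, Myog, Ckm, Myh3, Myh4, Cdkn1a, Ezh2, Mki67 and Ccnd1. Genes outside it are said to be named after their values were seen.

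The alternatives fixed before the data were examined were normexp background with offset 50, quantile and median-shift normalisation, the deposited series matrix, no filter and a filter on all 6 arrays, every probe on its own and the mean of probes, a variance trend with robust estimation, array weights, a block on the replicate number or on the slide, each replicate left out, a minimum fold of 2 and an estimated correlation. The files hold no mean pixel intensity, so normexp used the median pixel intensity. The slide block separated the scan of replicates 1 and 2 from that of replicate 3, with the shared sample as a random block. The 6 arrays as 6 samples, the fit fixed before the data were examined, became an alternative after the arrays were compared. Alternatives chosen after seeing the data were the shared sample as a random block, the first scan alone, leaving out the shared sample of either group, and an adjusted p of 0.1.

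The fit was tested on simulated data in 5 simulations of 28555 genes with 200 changed genes each, 2 samples against 2. Of genes changed by a log2 of 1, 0% passed the threshold and 92.2% had an unadjusted p under 0.05; of genes changed by 2, 57.2% passed. None of the calls had the wrong sign, 286 were true and 21 were false. A list shifted by 0.5 was called in 5 of 5 simulations, and 0 of 110 unshifted lists were called. Simulated genes were drawn independently of each other, with a spread unrelated to their level. Only 200 genes were changed, while the measured data had 6460 features with an unadjusted limma p under 0.05, where chance gives 1428. Benjamini-Hochberg adjustment depends on how many genes change, so the shares that passed need not hold for the measured data. For G2 and mitosis the measured data gave an estimated correlation of 0.886. The simulation therefore cannot show how often lists of correlated genes are called falsely.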

Results

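RNA from C2C12 cells, a mouse myoblast line that fuses into myotubes when serum is lowered, was hybridised to 6 single-colour Agilent arrays. The cells had received a control small interfering RNA (si-NC, 3 arrays) or one directed against the long non-coding RNA SYISL (si-SYISL, 3 arrays), followed by 2 days in differentiation medium with 2% horse serum. Each array carried 43020 non-control spots for 39429 probes, and 0 spots were saturated. The share of spots well above background was 78.2%, 84.6% and 79.0% on si-NC replicates 1 to 3 and 90.0%, 87.9% and 90.6% on si-SYISL replicates 1 to 3. The median local background was 42, 36 and 50 intensity units on the si-NC arrays and 34, 34 and 40.5 on the si-SYISL arrays. The small number of arrays limits the precision.

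Replicates 1 and 3 of si-NC differed by less than the noise between spots of the same probe, and so did replicates 1 and 3 of si-SYISL. Over 338 replicated probes, chi-square per probe was 0.212 and 0.167 in these pairs and 27.5 to 185 in the other 13 pairs of arrays. Each of the 2 pairs was averaged and counted as 1 sample, which left 2 samples in each group. The labels do not say that replicates were separate cultures, so the p-values measure only the spread between these samples.

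**Figure D1:**
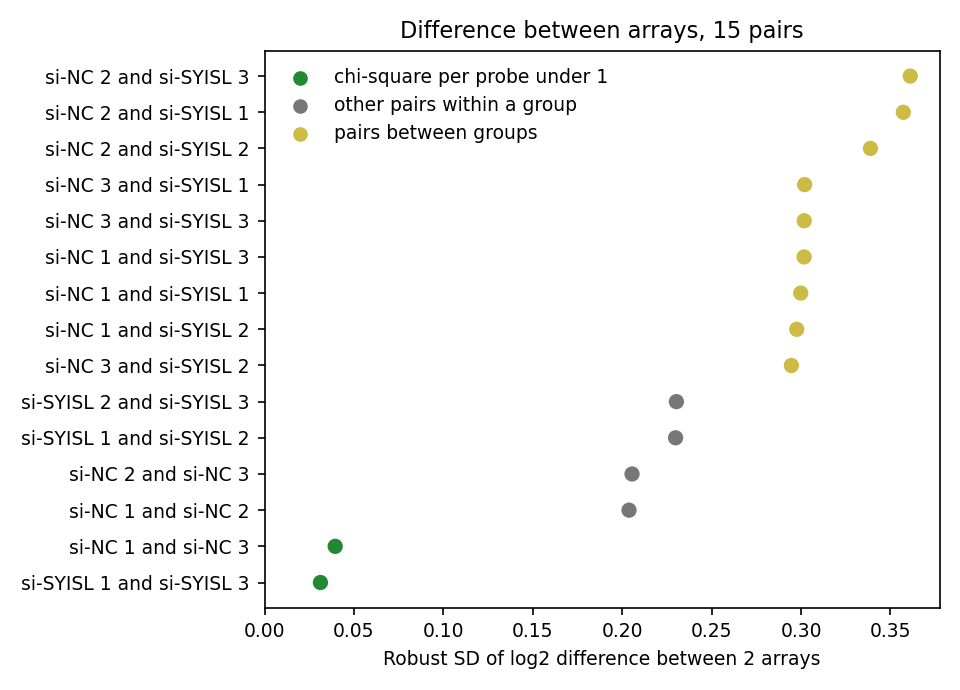
Robust standard deviation of the log2 difference between 2 arrays (x axis, log2 units) for each of the 15 pairs of arrays (y axis). Replicates 1 and 3 of si-NC (0.0395) and of si-SYISL (0.0313) lie far below the other pairs, which range from 0.204 to 0.361.

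The comparison of si-SYISL with si-NC asks which genes differ across the genome when SYISL is targeted in C2C12 cells on day 2 of differentiation. In camera with a preset correlation, genes of the contractile apparatus, of muscle calcium handling and energy supply, of the interferon response and of glycolysis were higher as lists in the si-SYISL samples, and genes of DNA replication and of mitosis were lower. None of these calls held with an estimated correlation (adjusted p = 0.573 to 0.730), and those of muscle calcium and energy genes and of the interferon response were lost without the si-SYISL sample of replicates 1 and 3 (adjusted p = 0.129 and 0.153). With 2 residual degrees of freedom, camera at an estimated correlation has little power. It cannot decide whether correlation between genes accounts for the calls. Relative to all genes, the list medians were 0.56 (log2) for the sarcomere and -0.64 for G2 and mitosis, which was -0.37 without si-SYISL replicate 2. No single gene passed the threshold over all genes: limma called 0 of 28555 features (18635 named genes and 9920 unnamed probes) at an adjusted p of 0.05, the smallest adjusted p being 0.0839. At an unadjusted p under 0.05 there were 6460 features, 4790 higher and 1670 lower, where chance gives 1428.

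The median log2 fold of all features was 0.16, higher in si-SYISL, and quantile normalisation reduced it to 0.03. Log2 differences of genes and lists are therefore given relative to that median, as si-SYISL minus si-NC ± SE with 2 samples in each group, while adjusted p-values test the difference before this subtraction. Folds given as lower bounds ("at least") are also before this subtraction. The median before subtraction was 0.36 in the dimmest of 4 equal groups of features and 0.08 in the brightest. Each list's median was also set against 10000 random lists of genes of like brightness. The share with a lower median was 26.4% for p53 targets, 6.65% for PRC2 components and 5.7% for inhibitors of myogenesis. It was 5.44% for cholesterol synthesis and 6.9% for neural and glial markers. These medians were thus not set apart from genes of like brightness. For the other called lists it was 100% or at most 0.01%. No probe was assigned to SYISL by the reference table used here, so the knockdown itself was not checked here. Synpo2, the gene within which the SYISL locus lies, differed by -0.29 ± 0.26 (adjusted p = 0.763), and before subtraction its sign depended on the probe, from -0.13 to 0.27 over 3 probes.

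**Figure D2:**
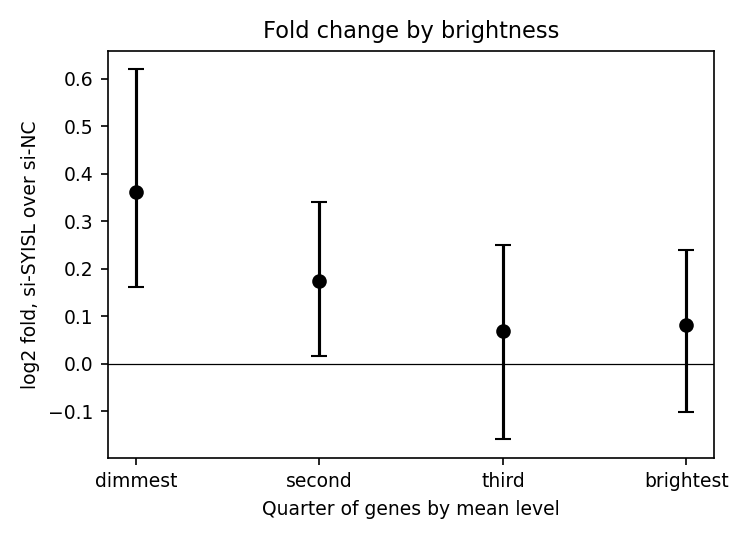
Median log2 fold of si-SYISL over si-NC before subtraction (points) with the lower and upper quartile (bars), for 4 groups of features ordered by mean level (x axis). The median falls from 0.36 in the dimmest group to 0.07 and 0.08 in the brighter ones.

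Of 45 measured sarcomere genes, which encode the contractile filaments, 30 rose and 1 fell when adjusted over the list alone, and 0 passed over all genes. The list was higher by camera (adjusted p = 2.82e-08), with adjusted p = 0.573 with an estimated correlation. Both si-SYISL samples lay above both si-NC samples for 38 of the 45 genes, against 46.3% of all features and 16.7% by chance. Mybpc2, the fast-muscle form of myosin-binding protein C, differed by 1.67 ± 0.12 and Tnnc2, the fast-muscle troponin C, by 1.21 ± 0.11, each with an adjusted p over all genes of 0.0839. The adult fast myosin Myh4 differed by 0.81 ± 0.13 (adjusted p = 0.102) and the embryonic myosin Myh3 by 0.62 ± 0.12 (adjusted p = 0.115). The gene that fell was Tmod1, which caps actin filaments (-0.66 ± 0.16, limma adjusted p over the list alone = 0.045), named after its value was seen; 0 fell without the sample of replicates 1 and 3 of either group. With normexp background the list's median was 0.37.

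Genes of muscle membrane, calcium and energy supply were also higher as a list (27 genes, median 0.34, camera adjusted p = 0.00543; adjusted p = 0.574 with an estimated correlation). Adjusted over the list alone, 12 rose and 0 fell, and 0 passed over all genes. Ckmt2, the mitochondrial creatine kinase of muscle, was not above background on any si-NC array and was at least 2.17-fold higher in si-SYISL. Pgam2, the muscle phosphoglycerate mutase, differed by 1.67 ± 0.16 (adjusted p = 0.0839) and Ckm, the cytosolic muscle creatine kinase, by 0.65 ± 0.15 (adjusted p = 0.124). Without the si-SYISL sample of replicates 1 and 3, the list's adjusted p was 0.129 and 6 members rose over the list alone, and without si-SYISL replicate 2, 7 rose.

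The myogenic regulatory factors were not called as a list (14 genes, median -0.01, mean -0.13, camera adjusted p = 0.196), and 0 of them passed over the list alone or over all genes. With a variance trend 2 fell over the list alone and 1 over all genes, and with the slide block 1 fell over the list alone. The median rested on single samples: it was -0.19 without si-NC replicate 2 (adjusted p = 0.0652), -0.08 without si-SYISL replicate 2, -0.11 without the si-SYISL sample of replicates 1 and 3, and 0.03 without that of si-NC, where 1 rose over the list alone. Myod1, which starts the muscle programme, differed by -0.78 ± 0.13 (adjusted p = 0.131) and Six4 by -0.58 ± 0.12 (adjusted p = 0.173). Myog, which acts later in differentiation, differed by -0.02 ± 0.17 (adjusted p = 0.602). The myoblast fusion list was not called (17 genes, median 0.03, mean 0.09, camera direction lower, adjusted p = 0.903), although 4 members rose over the list alone. They were Nfatc2 (1.23 ± 0.17, with 0.67 and 1.39 before subtraction at its 2 probes), the caveolin Cav3 (0.68 ± 0.13), the membrane-repair gene Dysf (0.36 ± 0.12) and the fusion protein gene Mymx (0.37 ± 0.11), of which Dysf and Mymx were named after their values were seen. Without 1 or the other si-SYISL sample 0 rose, and without the si-NC sample of replicates 1 and 3, or with every probe tested, 1 rose. The fusion median turned to -0.03 without si-NC replicate 2 and to -0.09 without the si-SYISL sample of replicates 1 and 3. Inhibitors of myogenesis and targets of Notch, BMP and TGF-beta were lower as a list (16 genes, median -0.23, camera adjusted p = 0.0384; adjusted p = 0.573 with an estimated correlation). Over the list alone 2 fell, the repressor Msc (-1.51 ± 0.11) and the Notch target Hey1 (-1.01 ± 0.16). Without si-NC replicate 2 or si-SYISL replicate 2 that list's adjusted p was 0.193 or 0.201, and with quantile normalisation it was 0.313. The median was -0.15 without si-NC replicate 2 and -0.10 with quantile normalisation. In the reported fit it was not set apart from those of lists of like brightness. Over the list alone 1 fell without si-NC replicate 2 or without 1 or the other si-SYISL sample.

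**Figure D3:**
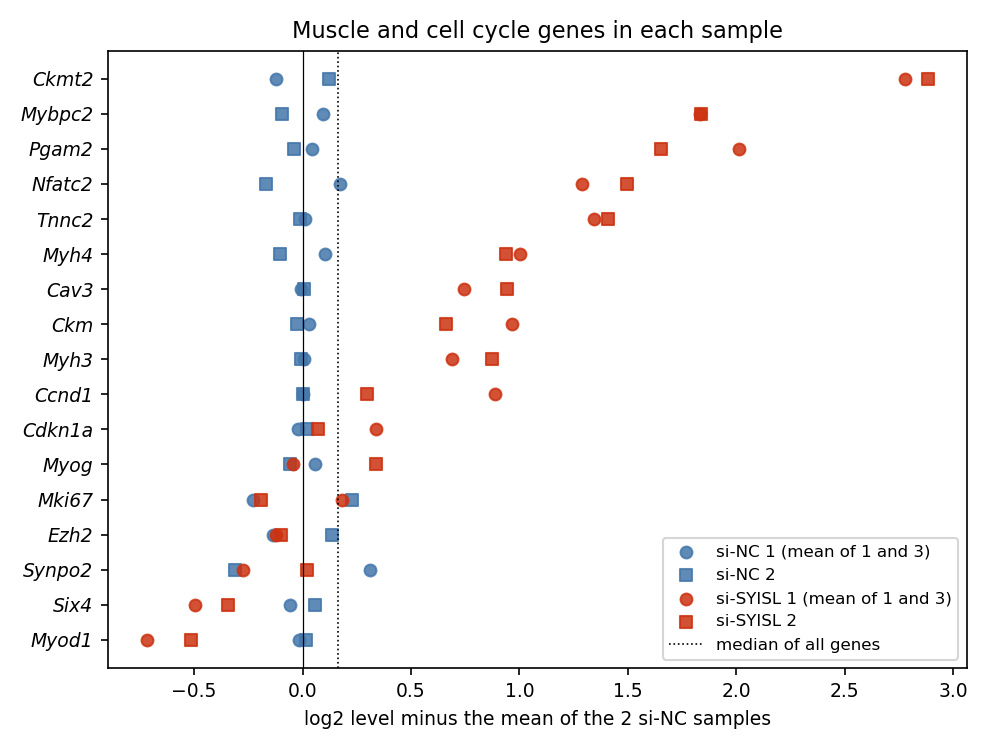
Log2 level of muscle and cell cycle genes in each of the 4 samples, minus the mean of the 2 si-NC samples (x axis); circles are the means of replicates 1 and 3, squares are replicate 2, and the dotted line is the median log2 fold of all features (0.16). For Mybpc2 and Tnnc2 both si-SYISL samples (red) lie right of both si-NC samples (blue), and for Myod1 both lie left.

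Genes of G2 and mitosis were lower as a list (33 genes, median -0.64, camera adjusted p = 5.91e-15; adjusted p = 0.573 with an estimated correlation). Adjusted over the list alone or over all genes 0 passed, while 33 of 33 lay below the median of all genes and 22 were lower in both si-SYISL samples than in both si-NC samples. Over the list alone 2 fell without the si-NC sample of replicates 1 and 3 and 6 with normexp background or a variance trend, and the list's median was -0.37 without si-SYISL replicate 2. The list's centred log2 level was 0.07 and 0.47 in the si-NC samples and -0.05 and -0.49 in the si-SYISL samples. The mitotic kinesins Kif11 (-1.15 ± 0.17, adjusted p = 0.122) and Kif2c (-1.12 ± 0.18, adjusted p = 0.125) had the smallest p of the list. The proliferation marker Mki67 differed by -0.17 ± 0.23 (adjusted p = 0.992).

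Genes of S phase and replication were lower as a list (33 genes, median -0.33, camera adjusted p = 4.24e-07; adjusted p = 0.573 with an estimated correlation), with 0 members past the threshold over the list alone or over all genes. Its median was -0.22 without si-SYISL replicate 2, and 5 members fell over the list alone with a variance trend. E2f2, a transcription factor of S-phase entry, differed by -0.80 ± 0.13 (adjusted p = 0.130) and Slbp, the histone mRNA binding protein gene, by -0.72 ± 0.11 (adjusted p = 0.127). Cell cycle inhibitors were not called (15 genes, median -0.16, camera adjusted p = 0.0542), but passed without the si-SYISL sample of replicates 1 and 3 (median -0.26, adjusted p = 0.0107). Without si-NC replicate 2 the median was -0.06. Over the list alone 0 passed, but 4 fell without si-SYISL replicate 2, and 2 rose without si-NC replicate 2 and 1 without the si-NC sample of replicates 1 and 3. Among them Cdkn2b was not above background on any si-NC array and was at least 3.35-fold higher in si-SYISL (adjusted p = 0.140), and Ccng2 differed by -0.75 ± 0.13 (adjusted p = 0.140). Cdkn1a, the p21 inhibitor, differed by 0.04 ± 0.14 (adjusted p = 0.395), with -0.45 and 0.20 before subtraction at its 2 probes. Ccnd1, the D-type cyclin, differed by 0.43 ± 0.23 (adjusted p = 0.227).

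**Figure D4:**
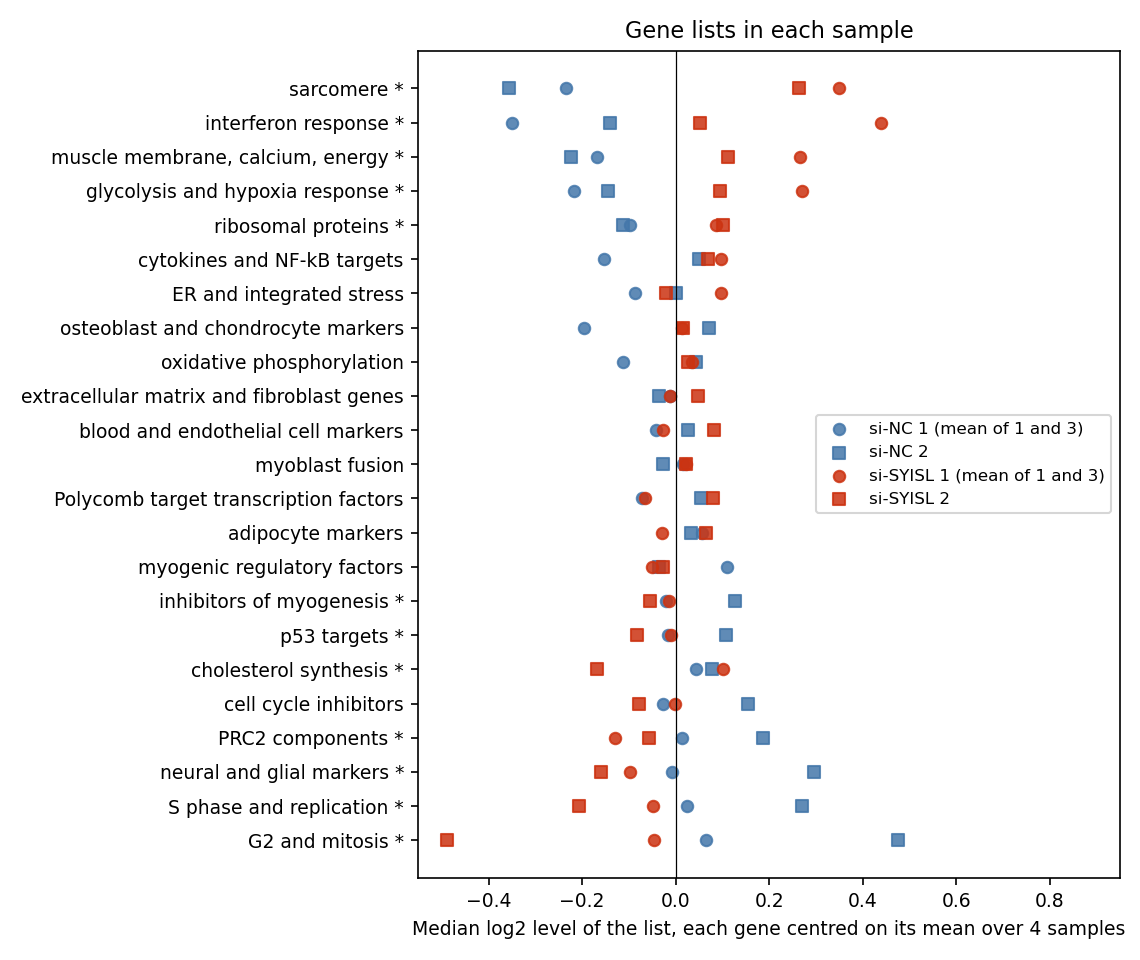
Median log2 level of each gene list in the 4 samples, each gene centred on its mean after the median of all features in each sample was subtracted (x axis); circles are the means of replicates 1 and 3, squares are replicate 2, and an asterisk marks lists with a camera adjusted p under 0.05. The sarcomere list lies at 0.35 and 0.26 in si-SYISL and at -0.24 and -0.36 in si-NC.

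Interferon response genes were higher as a list (32 genes, median 0.43, camera adjusted p = 0.00143; adjusted p = 0.730 with an estimated correlation). Adjusted over the list alone 15 rose and 1 fell, and 0 passed over all genes. That count depended on the processing: over the list alone 0 rose with quantile normalisation, the series matrix, every probe or the replicate block and without the sample of replicates 1 and 3 of either group, and 1 rose with no filter. Gbp2 differed by 0.55 ± 0.12 (adjusted p = 0.121) and Zbp1, a nucleic acid sensor, by 0.59 ± 0.13 (adjusted p = 0.122). The gene that fell was the antiviral Rsad2 (-0.82 ± 0.15), named after its value was seen, and 0 fell without any 1 of the 4 samples. The list's centred level was 0.44 in the si-SYISL sample of replicates 1 and 3 and 0.05 in si-SYISL replicate 2, and without the former the adjusted p was 0.153. Without si-SYISL replicate 2 the list's median was 0.66. Cytokines and NF-kB targets were not called (15 genes, median 0.10, camera adjusted p = 0.5), and the median turned to -0.09 without the si-NC sample of replicates 1 and 3. Of these, 0 passed over the list alone, but 1 rose without 1 or the other si-NC sample and 3 with a variance trend. With members below background in 1 group set to their bound, list medians before subtraction moved from 0.59 to 0.56 for the interferon response and from 0.26 to 0.15 for cytokines.

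Genes of glycolysis and the hypoxia response were higher as a list (21 genes, median 0.32, camera adjusted p = 0.000543; adjusted p = 0.573 with an estimated correlation). Adjusted over the list alone 8 rose and 0 fell, and 0 passed over all genes. Over the list alone 3 rose without replicate 2 of either group, 2 without the si-NC sample and 1 without the si-SYISL sample of replicates 1 and 3, and 17 with a variance trend. Without that si-SYISL sample the list's median was 0.16. Car9, a carbonic anhydrase induced by hypoxia, differed by 2.43 ± 0.27 (adjusted p = 0.0847) and Slc16a3, a lactate transporter, by 0.92 ± 0.15 (adjusted p = 0.104). Oxidative phosphorylation was not called (35 genes, median -0.02, mean 0.03, camera direction higher, adjusted p = 0.241). Over that list alone 2 rose, the muscle forms Cox8b (1.22 ± 0.11) and Cox6a2 (0.66 ± 0.12), while 0 rose without 1 or the other si-SYISL sample and 1 without 1 or the other si-NC sample. Ribosomal protein genes were higher as a list (36 genes, median 0.11, camera adjusted p = 0.00167; adjusted p = 0.574 with an estimated correlation), with 0 members past the threshold over the list alone, but 22 with a variance trend. That call was lost with quantile normalisation (median 0.06, adjusted p = 0.0905) and without si-NC replicate 2 (adjusted p = 0.193).

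Components of the Polycomb repressive complex PRC2, which methylates histone H3, were lower as a list (11 genes, median -0.26, camera adjusted p = 0.0459; adjusted p = 0.573 with an estimated correlation), with 0 members past the threshold over the list alone. Its catalytic subunit gene Ezh2 differed by -0.27 ± 0.14 (adjusted p = 0.624), Suz12 by -0.50 ± 0.14 (adjusted p = 0.247) and Ezh1 by 0.11 ± 0.12 (adjusted p = 0.255). The PRC2 median was not set apart from those of lists of like brightness. The list's adjusted p was 0.193 without si-NC replicate 2, 0.145 without si-SYISL replicate 2, 0.051 without the si-NC sample of replicates 1 and 3, and 0.269 with quantile normalisation, where the median was -0.16. Transcription factors that Polycomb represses in stem cells were not called (30 genes, median -0.03, camera adjusted p = 0.565), and 1 of them, Wt1, rose over the list alone (1.02 ± 0.13), where 0 rose with quantile normalisation or normexp background, without si-NC replicate 2 or without 1 or the other si-SYISL sample. Their median was -0.08 without si-SYISL replicate 2 or without the si-NC sample of replicates 1 and 3.

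The p53 targets were lower as a list (20 genes, median -0.15, camera adjusted p = 0.0214; adjusted p = 0.573 with an estimated correlation), with Plk2 at -1.27 ± 0.22 and Ccng1 at -0.66 ± 0.11. Cholesterol synthesis was lower as a list (20 genes, median -0.19, camera adjusted p = 0.0214; adjusted p = 0.719 with an estimated correlation). Neither median was set apart from those of lists of like brightness. In both lists 0 members passed over the list alone, while 4 p53 targets fell with a variance trend. Without si-SYISL replicate 2 the adjusted p was 0.255 for the p53 targets and 0.776 for cholesterol synthesis. It was 0.0578 for the p53 targets without si-NC replicate 2 and 0.0696 for cholesterol synthesis without the si-NC sample of replicates 1 and 3. With quantile normalisation it was 0.269 and 0.0524. The median of the p53 targets was -0.02 with quantile normalisation and -0.10 without si-SYISL replicate 2, and that of cholesterol synthesis was -0.02 without si-SYISL replicate 2 and -0.35 without the si-SYISL sample of replicates 1 and 3.

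Among markers of other cell types, the neural and glial list was lower (13 genes, median -0.14, camera adjusted p = 0.00543; adjusted p = 0.573 with an estimated correlation), and its adjusted p was 0.0767 without si-NC replicate 2 and 0.0514 without si-SYISL replicate 2. Over the list alone 6 fell and 1 rose; 2 fell without the si-SYISL sample of replicates 1 and 3, and 4 rose without si-NC replicate 2. Its median was -0.05 with normexp background, -0.10 without si-SYISL replicate 2, -0.33 with quantile normalisation and -0.42 with the filter on all 6 arrays. In the reported fit it was not set apart from those of lists of like brightness. The neuronal tubulin Tubb3 (-1.64 ± 0.15) and the neurofilament Nefm (-1.45 ± 0.13) were among those that fell, and Mbp, a myelin protein gene named after its value was seen, rose (0.95 ± 0.17). The lists of extracellular matrix and fibroblast genes (27 genes, median -0.06, mean -0.02, camera direction higher, adjusted p = 0.731) and of blood and endothelial markers (18 genes, median 0.01, adjusted p = 0.693) were not called and had 0 members past the threshold over the list alone, where 4 matrix genes rose with a variance trend. Adipocyte markers were not called (12 genes, median -0.06, adjusted p = 0.401), with Lpl lower over the list alone (-1.02 ± 0.12). Osteoblast and chondrocyte markers were not called (12 genes, median -0.01, mean 0.03, adjusted p = 0.903), with Alpl higher (0.80 ± 0.12) and Sox9 lower (1.79-fold before subtraction) over the list alone. The endoplasmic reticulum and integrated stress list was not called (18 genes, median -0.03, mean -0.09, camera direction higher, adjusted p = 0.903), with Pdia4, a protein disulfide isomerase, lower over the list alone (-2.12 ± 0.31). Without si-NC replicate 2 or without 1 or the other si-SYISL sample, 0 adipocyte and 0 osteoblast markers passed over the list alone, and 0 stress genes were lower without the sample of replicates 1 and 3 of either group. The sign of the median turned for extracellular matrix genes without the si-NC sample of replicates 1 and 3 (0.02), for blood and endothelial markers (-0.08) and stress genes (0.08) without si-SYISL replicate 2, and for blood and endothelial markers (-0.02), stress genes (0.05) and osteoblast markers (0.17) without si-NC replicate 2. The adipocyte median was -0.15 without si-NC replicate 2 and -0.12 without si-SYISL replicate 2, and over the list alone 2 adipocyte markers rose and 1 fell without the si-NC sample of replicates 1 and 3.

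The 12 higher and 12 lower named genes with the smallest p all had a limma adjusted p of 0.0839. The rule took only genes with both si-SYISL samples on one side of both si-NC samples. Cd52, a glycoprotein gene of lymphocytes, was not above background on any si-NC array and was at least 34.9-fold higher in si-SYISL. Mrap, an accessory protein of melanocortin receptors, differed by 4.12 ± 0.31. The other higher genes were Cyb561 (2.28 ± 0.17), Olfr39 (2.28 ± 0.16), Dhrs7c (1.60 ± 0.11), Galnt6 (1.57 ± 0.12, with 0.19 and 1.73 before subtraction at its 2 probes), the myelin gene Mog (1.56 ± 0.12), Mybpc2 and Ckmt2, and Kcnv1, Prss38 and Tmem121b, at least 2.02-fold, 1.80-fold and 1.45-fold higher because no si-NC array was above background. Among the lower genes, the amino acid transporter Slc38a5 differed by -3.88 ± 0.22 and Nap1l5 by -3.71 ± 0.29, while the sulfotransferase Chst8 was not above background on any si-SYISL array and was at least 6.18-fold lower. The others were Colec10 (-2.33 ± 0.14), Vgll4 (-1.83 ± 0.12), Mybl1 (-1.79 ± 0.11), Stmn4 (-1.75 ± 0.13), Septin10 (-1.69 ± 0.12), Pirb (-1.68 ± 0.12), Msc, Adgrd1 (-1.46 ± 0.11) and Fam81a (at least 2.37-fold lower). Lower bounds of folds are before subtraction of the median of all features.

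The count over all genes changed with the processing and with single samples: limma called 903 features, 560 higher and 343 lower, with a variance trend and robust estimation, 183 with normexp background, 1271 without the si-NC sample of replicates 1 and 3, and 292 without si-NC replicate 2. The position on the slide differed between the groups, 1 or 2 for si-NC and 3 or 4 for si-SYISL, so position and group cannot be told apart.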

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

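The reported fit of 2 samples against 2 was chosen after the arrays were compared, and the 6 arrays as 6 samples, fixed before, became an alternative then. The alternatives with the shared sample as a random block, with the first scan alone, without the shared sample of either group and with an adjusted p of 0.1 were chosen only after the results were seen. Values of genes are log2 folds before the median of all features is subtracted, and values of lists are camera adjusted p-values. The count of features past the threshold was 0, and it was 183 with normexp background (94 higher, 89 lower), 46 among features above background on all 6 arrays (17 and 29), 903 with a variance trend and robust estimation (560 and 343) and 83 with a slide block (35 and 48). It was 9762 with 6 arrays as 6 samples (7087 and 2675), which counts arrays that differ by less than spot noise as separate samples, 1026 with the shared sample as a random block (649 and 377), 1051 at an unadjusted p under 0.05 and at least 2-fold (709 and 342) and 251 at an adjusted p under 0.1 (157 and 94). It stayed 0 with quantile normalisation, median shift, the series matrix, no filter, every probe, the mean of probes, array weights, the replicate block, the first scan alone and a minimum fold of 2. Leaving out replicates gave 0 to 1271 features (0 to 999 higher, 0 to 272 lower), with 1271 without the si-NC sample of replicates 1 and 3, 292 without si-NC replicate 2, and a lone sample assumed to vary like the other group. The median residual SD fell with brightness, from 0.2535 in the dimmest of 4 equal groups of features through 0.1574 and 0.1215 to 0.08778 in the brightest. The reported fit did not model this fall, and the fit with a variance trend did. How much of its 903 calls this accounts for was not tested. Other than for the 6-array fit, the cause of the changed counts was not tested.

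Of the 12 called lists, sarcomere, S phase and replication, G2 and mitosis, and glycolysis and hypoxia response stayed past the threshold in all 24 alternatives except the estimated correlation, and no list was called with that. The estimated correlation gave 0.573 for these 4 lists and for p53 targets, PRC2 components, inhibitors of myogenesis and neural and glial markers, 0.574 for muscle membrane, calcium and energy genes and for ribosomal proteins, 0.73 for interferon response and 0.719 for cholesterol synthesis. With normexp background PRC2 components had 0.0785, inhibitors of myogenesis 0.0683 and cell cycle inhibitors 0.0373. With quantile normalisation and with the series matrix, p53 targets had 0.269 and 0.266, PRC2 components 0.269 and 0.266, inhibitors of myogenesis 0.313 and 0.312, cholesterol synthesis 0.0524 and 0.0527, and ribosomal proteins 0.0905 and 0.0887. With the filter on all 6 arrays, p53 targets had 0.0529, PRC2 components 0.0853, inhibitors of myogenesis 0.0824, cholesterol synthesis 0.0529 and cell cycle inhibitors 0.024. With a variance trend, PRC2 components had 0.0515, inhibitors of myogenesis 0.0595 and oxidative phosphorylation 0.0317, which is past the threshold. PRC2 components had 0.0665 with the slide block and 0.0514 with the first scan alone. With 6 arrays as 6 samples, p53 targets had 0.0916, PRC2 components 0.0843, inhibitors of myogenesis 0.0843 and cholesterol synthesis 0.111, and with the random block p53 targets had 0.0543, PRC2 components 0.0642 and inhibitors of myogenesis 0.0594. Cell cycle inhibitors had 0.0488 with no filter, 0.00664 with every probe, 0.00767 with the mean of probes, 0.0498 with array weights and 0.043 with the replicate block. The cause of these changes was not tested.

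Leaving out replicates gave 0.00225 to 0.129 for muscle membrane, calcium and energy genes, 0.0107 to 0.213 for cell cycle inhibitors, 0.00245 to 0.255 for p53 targets, 0.0404 to 0.193 for PRC2 components, 1.22e-07 to 0.153 for interferon response, 0.0185 to 0.201 for inhibitors of myogenesis, 0.00398 to 0.0767 for neural and glial markers, 3.25e-05 to 0.776 for cholesterol synthesis and 0.00131 to 0.193 for ribosomal proteins. Among lists that were not called, the direction turned for myoblast fusion with normexp background (0.834), quantile normalisation (0.886), the series matrix (0.882), the mean of probes (0.884) and the variance trend (0.978), and on leaving out replicates (0.846 to 0.983). It turned for osteoblast and chondrocyte markers with quantile normalisation (0.936) and the series matrix (0.94), and for the endoplasmic reticulum and integrated stress list with the median shift (0.991) and the mean of probes (0.915). Leaving out replicates gave 0.427 to 0.947 and 0.509 to 0.946 for these, 0.235 to 0.994 for Polycomb target transcription factors and 0.697 to 0.947 for extracellular matrix and fibroblast genes.

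Of 1737 values of the 76 named genes under alternatives, 1715 kept their sign, 22 had the other sign and 286 were past the threshold, in 71 genes at least once. The alternatives that nearly repeat another count in these numbers. Synpo2 had 0.25 with every probe and 0.13 with the mean of probes, and -0.44 to 0.18 on leaving out replicates. Cdkn1a had -0.45 with every probe and -0.12 with the mean of probes. Myog ranged from -0.05 to 0.34 and Mki67 from -0.23 to 0.22 on leaving out replicates. Arrays numbered alike deviated from their group means with correlations across genes of -0.005, -0.031 and -0.037. Some arrays of each group were near-identical, so these values rest on much the same difference within each group. They therefore cannot decide whether the numbers pair the samples. Signal over background limits the dim probes: 1005 features were above background on no si-NC array, and their folds are lower bounds.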

Other observations

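Of the tests in this part, those of 1 RNA sample on 2 arrays and of an unequal share of dividing cells were chosen only after the result was seen, and the genes of the next paragraph were chosen after their values were seen.

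Several genes outside the fixed lists differed by large amounts, none of them past the threshold over all genes. Log2 differences are relative to the median of all features, ± SE with 2 samples in each group, and lower bounds of folds are before this subtraction. The secreted protease Pcsk5 differed by 3.50 ± 0.44 (limma adjusted p = 0.0943). The epithelial keratins Krt18 (2.98 ± 0.50) and Krt8 (2.26 ± 0.26), the placental glycoprotein Psg21 (1.54 ± 0.20) and the bone proteoglycan Omd (2.05 ± 0.18) were higher in both si-SYISL samples. The steroid enzymes Hsd3b6 (3.02 ± 0.29), Hsd3b1 (2.38 ± 0.37) and Cyp11a1 (1.49 ± 0.30) were also higher in both. Fabp7, a fatty acid binding protein gene, was not above background on any si-NC array and was at least 7.10-fold higher. Lower in both si-SYISL samples were Cdk2, a kinase of the G1 to S transition (-3.40 ± 0.29), Rictor, a subunit of mTOR complex 2 (-2.83 ± 0.41), and the chromatin protein Hmgb1 (-2.21 ± 0.34), whose 7 probes ranged from -2.09 to -0.43 before subtraction. The demethylase Kdm3b differed by -3.14 ± 0.27 at its brighter probe, while its 2 probes read -2.98 and 2.14 before subtraction.

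A hypothesis from Mrap, Cyp11a1, Hsd3b1 and Hsd3b6 was that genes of steroid hormone synthesis rise together. The 16 other measured genes of the pathway, listed before their values were seen, had a camera p of 0.0596 with direction lower and a median of -0.13, so the hypothesis found no backing. A hypothesis from Krt8, Krt18 and Psg21 was that genes of trophoblast and placenta rise together. The 20 other measured genes of that list had a camera p of 0.119 with direction higher, which missed the threshold set before the test. Their median of 0.31 lay above 99.8% of 10000 lists of like brightness and 4 of them rose over the list alone, so this may be followed up, but the test set in advance did not call it.

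Replicates 1 and 3 of each group differed by less than spot noise. For separate arrays, spot deviations were predicted to be no more alike than in other pairs. They correlated with at least 0.914 across spots, against at most 0.540 elsewhere. The pairs shared 3 and 6 non-uniform spots where other pairs shared 0. If 1 hybridised array had been scanned on 2 occasions, local background of single spots was predicted to correlate above 0.5 and, if not, below 0.3; it correlated with 0.203 and 0.223, which is below that bound, against at most 0.110 in the 13 other pairs. The reading was changed to open after this value was seen, because the bound took no account of noise: pixels of the local background have a standard deviation of 7.75 to 9.90, against a robust spread between spots of at most 2.22, and the highest correlation this noise allows was not computed. The background test therefore cannot decide for or against a rescan, with 1 and 0 background non-uniform spots shared. Signals of negative controls correlated with 0.926 and 0.848 in these pairs, against at most 0.631 elsewhere. These pairs were also the only ones at the same slide position. The spot deviations and the shared non-uniform spots argue against separate arrays only if arrays at the same position do not share such patterns. That could not be tested, as no other pair had the same position. A rescan was not shown by the test set in advance, and no biological explanation was tested.

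Dim probes read higher in si-SYISL. Scaled negative controls were negative after background subtraction in all 4 samples (-13.7 and -7.04 in si-NC, -5.56 and -7.45 in si-SYISL). The controls were read in the background-subtracted signal and the shift in the processed signal, which is another value. They therefore cannot show whether background was left in the signals compared. A background subtraction that differed between the groups may still contribute. The controls were 3.85 units higher in si-SYISL, where the shift needs 11.1, but the 4 samples overlapped. A general rise of weakly expressed genes was not tested apart from such a difference in subtraction.

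The sarcomere list was higher and the G2 and mitosis list lower. The dim-probe shift would give medians like those of lists of like brightness, but the sarcomere median lay above 100% and the G2 and mitosis median above 0% of 10000 such lists. An unequal share of dividing cells between samples may contribute to the G2 and mitosis gap, since the larger gap within a group was 0.824 of the gap between groups (0.410 and 0.443 within, -0.538 between). The same share, at the slopes within groups, predicts a sarcomere gap of 0.159 from si-NC and -0.104 from si-SYISL, against 0.601 measured. Each slope rests on 2 samples and the slopes differ in sign, so they set no firm bound. An effect of the SYISL siRNA, on its target or elsewhere, stays open for both lists, as does slide position, which follows the groups.

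With the 6 arrays as 6 samples, 1 of the 10 splits into 3 and 3 gave as many genes as the real one, the real one itself, with 9762, and the highest other split gave 0. Of the 9 other splits, 8 part replicates 1 and 3 of a group, so that near-identical arrays stand against each other, and the 1 that keeps both pairs together gave 0. The 10 splits are too few for a share under 0.05.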
